A study of Mus musculus with 74 samples.

How the data were processed

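The libraries were MARS-seq libraries, which tag the 3' end of transcripts, from sorted mTEChi (medullary thymic epithelial cells with high MHC class II) of mice aged 4 to 7 weeks. Per the labels' protocols, thymi were dissociated with Liberase TH and DNase and RNA was captured on Dynabeads. Per the submitters' processing notes, bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 were used with build mm10. Their settings, the annotation, the use of strand and the collapse of molecular identifiers are not stated.

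The authors deposited 6 tables, 4 for C57BL/6 (B6) and 2 for NOD lines, each with raw counts per gene and library, and only these raw counts entered the tests. Each table lists only genes with a highest count of at least 6. The authors' log2 fold change, taken as the first-named group over the second, and the authors' p-value and adjusted p-value per comparison were set beside a DESeq2 refit of the raw counts. In the table with the C313Y and null lines the authors also deposited normalized signal values (counts divided by size factors) and log2 values after ComBat, a batch correction, which were used only to see which libraries it treated as batches. The deposited normalized counts and regularized log2 values of the other tables were not used here.

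Groups came from the titles and genotype labels: 73 libraries in 21 groups. A further library of the B6 null line, wt_438, is titled wild type but has the genotype label Aire -/-, so it entered no group. The 5 NOD wild-type libraries set against +/C313Y include 2 that are titled C313T. The 3 wild-type libraries set against -/C313Y have the same title form as those mutants. NOD Aire-/- was set against Aire+/-, as its title form has no wild type. Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

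Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust dispersion, TMM factors, filterByExpr on groups), with all groups of a table in one fit so that they share the spread estimate. Differences between alleles on B6 were tested in a joint fit of 4 tables over 14815 shared genes, each effect against the wild type of its own line. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Standard errors are those of the log2 fold change from that test, and values in CPM are counts scaled to library size with the SD over libraries.

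The 24 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted over the lists of a comparison. Beside each test stand the members called over all genes, and those called when adjusted over the list alone where that differs. Of 7 erythroid markers only 2 are in any table, and that list was not tested. The Aire-induced set is the 1294 genes called at least 2-fold lower in B6 Aire-/- than in wild type. Its direction was tested with fry (limma), which asks whether the set moves one way on balance (adjusted over the comparisons other than the one that chose the set), and its share of each library's counts with a two-sided exact permutation test. In the B6 null line this is circular. The number of genes with at least 1 count, after thinning each library to the smallest total of its table, was compared with the same test.

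Named genes followed a fixed rule. They were Aire in each comparison, up to 8 genes each way with the largest called log2 change, CPM ranges that did not overlap and a mean of at least 5 CPM in the higher group (up to 4 each way for differences between lines, without the overlap condition), and up to 4 members of each list with a called member or a passing set test. Where fewer than 10 genes were called, all were eligible. Symbols that start with Gm and a digit or end in Rik were passed over in the second part. A fold against a group without any count is given as a lower bound, computed with a floor of 3 counts over the group. A fold against a group with 1 to 3 counts is given as the ratio with its 95% counting interval. Such intervals and floors cover counting error only.

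In simulated data with 200 changed genes, edgeR recovered 31.3% of 1.5-fold, 73.1% of 2-fold and 98.5% of 4-fold changes for B6 Aire-/- against wild type, and 7.46%, 17.9% and 77.3% for +/C313X against wild type. At most 14 false calls and 0 calls of the wrong sign occurred in any of the 21 simulated comparisons.

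Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, only the compared groups in the fit, each library left out in turn, other wild types on NOD, a replicate block, other definitions of the Aire-induced set (no fold limit, the top 200 genes by p, without its 5 most abundant genes), a minimum of 3 counts for a detected gene, and the estimated correlation. A sex term, leaving out the libraries titled C313T, and a second Aire-induced set from the Y86C and C442G homozygotes were chosen after seeing the data. Only groups of at least 4 libraries were screened for outliers, in 24 tests, and 0 were found. Gene positions came from the GRCm38 annotation. Python 3.11.15 and matplotlib 3.10.9 drew the figures.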

Results

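The data were 74 MARS-seq libraries, a method that sequences tags from the 3' end of transcripts, from mTEChi cells. mTEChi are medullary thymic epithelial cells with high MHC class II, the cells that make AIRE, a nuclear protein through which the thymus displays proteins of other organs to developing T cells. The mice were 4 to 7 weeks old and carried mutant alleles of Aire on the C57BL/6 (B6) or NOD background. The authors' raw count tables held 17853 genes in at least 1 of 6 tables, and 14637 genes in all of them. The alleles were a null, and the changes Y86C, V303M, C313Y, C442G and C313X, the last a stop.

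The 73 assigned libraries fell into 21 groups. The B6 null line had 3 wild-type, 5 heterozygous and 4 homozygous libraries, the Y86C line 3 of each, the C313X line 3, 2 and 3, and the C442G line 3, 5 and 6. On NOD, the V303M line had 3 of each genotype. A shared NOD table had 3 Aire+/- and 3 Aire-/- libraries, 4 +/C313Y libraries with 5 wild-type libraries of the same title form, and 3 -/C313Y libraries (1 null and 1 C313Y allele) with 3 wild-type libraries of their own title form. Total counts per library ran from 1016619 to 7225403, both ends in the V303M line, and the most abundant gene took between 1.07% and 3.63% of a library. Library totals ran from 1425904 to 3618266 in the B6 null line, 1699217 to 3614344 in Y86C, 1087464 to 3701973 in C313X, 1751301 to 4189258 in C442G and 1536436 to 3692601 in the shared NOD table.

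In the annotation of build GRCm38, Aire lay on chromosome 10 from 78030022 to 78043610 on the minus strand. Dnmt3l, a germline partner of DNA methyltransferases, lay head to head with it on the plus strand from 78041947 to 78063622, so that the genes overlapped by 1664 bp. Icosl, the ligand of the T cell costimulator ICOS, followed from 78069302 to 78083913. In transcript Aire-204, with 552 residues over 14 exons, Y86 lay in exon 2 at 78042954 to 78042956. V303 and C313 lay in exon 8 at 78037965 to 78037967 and 78037935 to 78037937. At the residue number of C442G that transcript has glutamate, not cysteine, so no position is given for it.

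**Figure D1:**
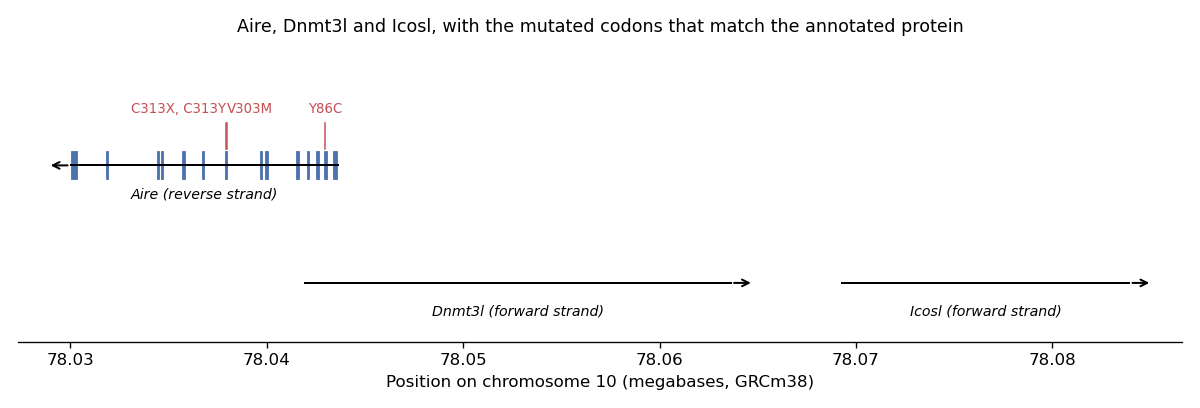
Map of chromosome 10 in GRCm38 coordinates (megabases), with gene spans as arrows, exons of Aire as boxes and marks at the codons for Y86C, V303M and C313X or C313Y. The 5' ends of Aire and Dnmt3l overlap by 1664 bp on opposite strands.

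Aire transcript, the targeted gene, did not fall in any mutant group. It averaged 2125 ± 79.6 CPM (counts scaled to library size, SD, n = 3) in B6 wild type of the null line, 2427 ± 465 in 5 heterozygotes and 3162 ± 364 in 4 Aire-/- libraries. The homozygous point mutants held 3553 ± 191 CPM for Y86C against 1685 ± 71.9 in wild type (n = 3 each), 4292 ± 225 for C313X against 2303 ± 555 (n = 3 each), and 3974 ± 276 (n = 6) for C442G against 2161 ± 112 (n = 3). On NOD it was 3192 ± 232 in Aire-/- and 2272 ± 288 in Aire+/- (n = 3 each), 3746 ± 744 in +/C313Y (n = 4), 3834 ± 317 in -/C313Y (n = 3), and 2625 ± 525 (n = 5) and 2626 ± 365 (n = 3) in the wild types of the respective title forms. V303M homozygotes held 2283 ± 189 CPM against 1919 ± 37.9 in wild type (n = 3 each). The labels do not say which part of the gene the null allele lacks, and a 3' tag outside a deleted part checks nothing about a knockout.

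**Figure D2:**
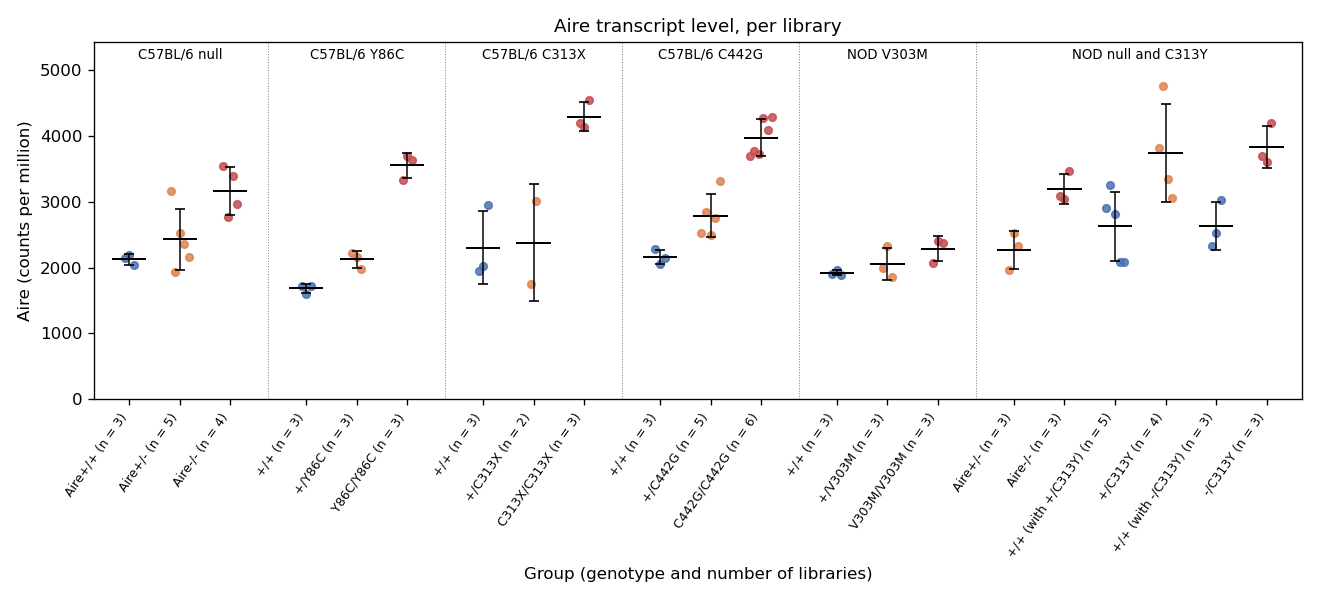
Aire level in CPM (vertical axis) in each library, by group (horizontal axis), with dots for libraries, black lines for group means and error bars for 1 SD. The homozygous C313X group has the highest mean, 4292 CPM, and the Y86C wild type the lowest, 1685 CPM.

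The first comparison asked what B6 mTEChi express without functional AIRE. Most known Aire-induced antigens and most pancreas, liver and gut genes on the lists fell, the insulin and somatostatin genes among them. At the same time antigen-presentation and tight-junction genes of mature mTEC rose, while most interferon-stimulated and proliferation genes and 6 of 15 keratinocyte-like genes fell. These 4 list tests passed with the preset correlation between genes but not with an estimated one. Aire itself rose by 0.68 ± 0.14 on the log2 scale (adjusted p = 0.00197). In total, edgeR called 4650 of 12700 genes, 2252 higher and 2398 lower, of which 598 rose and 1294 fell at least 2-fold.

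The largest rises included Rgr, a retinal opsin, with a log2 change of 3.26 ± 0.62, Ctla4, an inhibitory receptor best known from T cells, with 3.15 ± 0.25, and Acot12, a thioesterase, with 2.90 ± 0.54. Among the genes that fell most, the insulin gene Ins2 was 389-fold (95% counting interval 69.1 to 15400) lower and Hoxb13, a posterior homeobox gene, 225-fold (95% counting interval 39.8 to 8970) lower. Pnliprp1, a pancreatic lipase relative, had no count in Aire-/- and was at least 38.1-fold lower, and Il17b, a cytokine, at least 32.5-fold lower. Avp, the vasopressin gene, fell by 6.76 ± 0.29 on the log2 scale.

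For the known Aire-induced antigens, of the 27 measured members, 1 rose, 24 fell and 2 did not pass (adjusted over the list alone, 1 rose and 25 fell, camera adjusted p = 3.56e-17, adjusted p = 0.00044 with an estimated correlation). Sst, the somatostatin gene, changed by -5.52 ± 0.34 and Pcp4, a neuronal calmodulin regulator, by -3.12 ± 0.16. Among pancreas genes, of the 18 measured, 0 rose, 13 fell and 5 did not pass (camera adjusted p = 5.11e-10, adjusted p = 0.0162 with an estimated correlation), with the elastase gene Cela3b at -5.98 ± 0.43. In the liver list, of the 15 measured genes, 0 rose, 13 fell and 2 did not pass (camera adjusted p = 2.78e-08, adjusted p = 0.0162 with an estimated correlation), and in the gut list of the 24 measured genes, 1 rose, 19 fell and 4 did not pass (camera adjusted p = 2.29e-10, adjusted p = 0.0365 with an estimated correlation).

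In the mature mTEC list, of the 21 measured genes, 16 rose, 1 fell and 4 did not pass (camera adjusted p = 4.5e-05, adjusted p = 0.164 with an estimated correlation), led by the claudins Cldn4 and Cldn3 at 1.25 ± 0.09 and 1.23 ± 0.11 and by H2-DMb1, which loads peptides on MHC class II, at 0.73 ± 0.09. In the NF-kB list, of the 15 measured genes, 8 rose, 2 fell and 5 did not pass (camera adjusted p = 0.00511, adjusted p = 0.118 with an estimated correlation), with the kinase gene Map3k14 at 1.19 ± 0.10. Interferon-stimulated genes went down: of the 18 measured, 2 rose, 12 fell and 4 did not pass (camera adjusted p = 0.00104, adjusted p = 0.257 with an estimated correlation), with Ifit3 at -2.13 ± 0.21 and Isg15 at -1.53 ± 0.16 but Ifit1 at 0.72 ± 0.09. Proliferation genes went down: of the 15 measured, 0 rose, 12 fell and 3 did not pass (camera adjusted p = 0.000143, adjusted p = 0.257 with an estimated correlation), Mcm5, a replication helicase subunit, at -0.88 ± 0.15. In the keratinocyte-like list, of the 15 measured genes, 0 rose, 6 fell and 9 did not pass (camera adjusted p = 0.0106, adjusted p = 0.396 with an estimated correlation), with the keratin gene Krt1 at -3.13 ± 0.46, and in the immature mTEC list of the 9 measured genes, 0 rose, 6 fell and 3 did not pass (camera adjusted p = 0.0124, adjusted p = 0.228 with an estimated correlation), with Krt15 at -2.19 ± 0.33.

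The comparison of Aire+/- with wild type asked what the loss of a single copy does. Few genes moved, and the mature mTEC claudins and the neighbour Dnmt3l were among those that rose. Cldn4 and Cldn3 changed by 0.52 ± 0.09 and 0.52 ± 0.11, Il1rn, an interleukin-1 antagonist, by 0.48 ± 0.08, the chemokine gene Cxcl1 by 0.68 ± 0.16, and Bmx, a kinase of tuft cells, by 1.07 ± 0.22. Dnmt3l rose by 1.18 ± 0.16 on the log2 scale (adjusted p = 0.0011) and Samd15, of unknown function, by 1.93 ± 0.44. The liver cytochrome gene Cyp1a2 changed by -0.89 ± 0.18, the fatty acid carrier Fabp3 by -1.45 ± 0.27, the retinoic acid carrier Crabp1 by -0.78 ± 0.13 and Btbd17 by -2.11 ± 0.40. Aire changed by 0.20 ± 0.13 on the log2 scale (adjusted p = 0.708), which did not pass.

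In all, edgeR called 61 of 12700 genes, 48 higher and 13 lower. In the tuft list, of the 18 measured genes, 1 rose, 0 fell and 17 did not pass (adjusted over the list alone, 3 rose and 0 fell, camera adjusted p = 3.75e-05, adjusted p = 0.543 with an estimated correlation). The genes called at least 2-fold lower in Aire-/- form the Aire-induced set of 1294 genes used from here on, and in Aire+/- 12 of them fell, 69.5% lay below 0 and the median was -0.20 (fry adjusted p = 0.00126). Of 598 genes raised at least 2-fold in Aire-/-, 37 also rose in Aire+/-. Both sets were chosen with the same wild-type libraries, which moves them the same way without any effect, so neither is independent evidence. Leaving out 1 library brought the count of calls to 39 without het_440 and to 23, 16 and 15 without wt_430, wt_432 and wt_434.

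Aire-/- against Aire+/- differed nearly as much as against wild type, so the step from 1 copy to none carried most of the change. Aire rose by 0.47 ± 0.12 on the log2 scale (adjusted p = 0.0085), and edgeR called 4287 of 12700 genes, 2068 higher and 2219 lower. Ctla4 changed by 3.08 ± 0.21, Rgr by 2.33 ± 0.47 and Acot12 by 2.76 ± 0.45, while Ins2 was 392-fold (95% counting interval 69.9 to 15500) lower and Il17b at least 37-fold lower. Of 27 measured antigen-list members, 1 rose, 25 fell and 1 did not pass (camera adjusted p = 3.59e-20, adjusted p = 0.000228 with an estimated correlation). Krt15, of immature mTEC, changed by -2.46 ± 0.30 and Rsad2, an antiviral enzyme, by -2.31 ± 0.29.

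Y86C lies in the CARD domain, through which AIRE assembles, and its homozygote asked what a change there does. Mature mTEC markers rose. Keratinocyte-like, tuft and fibroblast genes fell, in lists that passed with the preset correlation but not with an estimated one. Aire rose by 1.32 ± 0.08 on the log2 scale (adjusted p = 6.21e-15), the largest estimate of any line. In total, edgeR called 6599 of 13309 genes, 2886 higher and 3713 lower, of which 798 rose and 2480 fell at least 2-fold.

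Ptchd4, a patched-family gene, changed by 4.15 ± 0.34, Ctla4 by 3.37 ± 0.27 and Stac, a calcium channel adaptor, by 2.93 ± 0.19. Without any count in the mutant were Hbb-y, an embryonic globin (at least 271-fold lower), Obp2a, an odorant carrier (at least 235-fold lower), Calb2, the calretinin gene (at least 214-fold lower), and Crybb2, a lens crystallin (at least 105-fold lower). Ppy, which encodes pancreatic polypeptide, was 2000-fold (95% counting interval 359 to 79200) lower.

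Of 29 measured antigen-list members, 1 rose, 27 fell and 1 did not pass (camera adjusted p = 1.1e-14, adjusted p = 0.00852 with an estimated correlation), with Csn1s2a, a casein, at -5.86 ± 0.21 and Npy, neuropeptide Y, at -4.82 ± 0.19. Of 21 measured mature mTEC genes, 18 rose, 2 fell and 1 did not pass (camera adjusted p = 1.78e-06, adjusted p = 0.0197 with an estimated correlation). Tnfrsf11b, a decoy for the mTEC growth factor RANKL, changed by 1.34 ± 0.09 and its receptor Tnfrsf11a by 0.99 ± 0.09. In the keratinocyte-like list, of the 15 measured genes, 0 rose, 14 fell and 1 did not pass (camera adjusted p = 8.56e-06, adjusted p = 0.0728 with an estimated correlation), with Cdsn, which holds cornified cells together, at -3.59 ± 0.46. The tuft list went down: of the 18 measured, 1 rose, 13 fell and 4 did not pass (adjusted over the list alone, 1 rose and 14 fell, camera adjusted p = 0.0101, adjusted p = 0.429 with an estimated correlation), with Dclk1 at -1.95 ± 0.29 and Trpm5, a taste channel, at -1.62 ± 0.23. In the fibroblast and endothelial list, of the 9 measured genes, 1 rose, 7 fell and 1 did not pass (camera adjusted p = 0.0164, adjusted p = 0.218 with an estimated correlation), with the collagen gene Col1a1 at -5.48 ± 0.27 and Dcn, a proteoglycan, at 2.36 ± 0.12.

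In Y86C heterozygotes fewer genes were called. Aire rose by 0.39 ± 0.08 on the log2 scale (adjusted p = 0.0035), a part of the mature mTEC genes rose and a part of the organ genes fell. In total, edgeR called 448 of 13309 genes, 309 higher and 139 lower, while DESeq2 called 250 higher and 49 lower, so the lower share was 31.0% with edgeR and 16.4% with DESeq2. H2-Eb1 and H2-Aa, MHC class II chains, changed by 0.50 ± 0.12 and 0.41 ± 0.11, and Tnfrsf11b by 0.50 ± 0.09. In the mature mTEC list, of the 21 measured genes, 6 rose, 0 fell and 15 did not pass (adjusted over the list alone, 12 rose and 0 fell, camera adjusted p = 2.48e-05, adjusted p = 0.112 with an estimated correlation). Of 29 measured antigen-list members, 0 rose, 5 fell and 24 did not pass (adjusted over the list alone, 0 rose and 6 fell, camera adjusted p = 0.000849, adjusted p = 0.167 with an estimated correlation), with Fabp2, the gut fatty acid carrier, at -0.93 ± 0.19 and Npy at -0.55 ± 0.12. Markers of other cells rose too, the cortical epithelial genes Tbata and Ccl25 by 0.61 ± 0.08 and 0.57 ± 0.08, Batf3 of the myeloid list by 0.81 ± 0.15 and Coro1a of the thymocyte list by 0.59 ± 0.13.

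Among the largest single changes, Slc24a4, an ion exchanger, changed by 1.35 ± 0.26, Fam19a1, a chemokine-like neural gene, by 1.30 ± 0.29, Fam150b, a ligand of the kinase ALK, by -2.38 ± 0.56 and Gpbar1, a bile acid receptor, by -1.88 ± 0.35. Of the Aire-induced set, 94 genes fell, 82.5% lay below 0 and the median was -0.32 (fry adjusted p = 3.57e-05). Leaving out 1 library gave 242 calls without wild type 2, 218 without wild type 3, 290 without heterozygote 14 and 253 without heterozygote 3.

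C313X is a stop codon within the first PHD finger, a zinc domain that reads histone tails, and asked what a truncated AIRE leaves. Homozygotes again lost organ transcripts, and a part of the macrophage and thymocyte markers in the sorted cells were lower too, in lists that did not pass with an estimated correlation. Aire rose by 1.09 ± 0.24 on the log2 scale (adjusted p = 0.00913), and edgeR called 3147 of 13626 genes, 1070 higher and 2077 lower. Spock3, a neural proteoglycan, changed by 3.80 ± 0.55, Fam19a1 by 3.19 ± 0.52 and Ctla4 by 2.80 ± 0.54. Among genes without a count in the mutant, Ppy was at least 421-fold lower, Amelx, an enamel protein, at least 285-fold lower, Cyp1a2 at least 232-fold lower and Nppa, a heart hormone, at least 213-fold lower.

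Of 26 measured antigen-list members, 0 rose, 21 fell and 5 did not pass (adjusted over the list alone, 1 rose and 22 fell) with a median log2 change of -4.31 (-3.99 with genes absent from a group at their bound, camera adjusted p = 2.57e-14, adjusted p = 0.0347 with an estimated correlation). Pancreas genes fell: of the 19 measured, 0 rose, 16 fell and 3 did not pass (camera adjusted p = 6.94e-13, adjusted p = 0.0352 with an estimated correlation), with the peptide gene Pyy at -6.50 ± 0.34. Of 21 measured mature mTEC genes, 5 rose, 1 fell and 15 did not pass (adjusted over the list alone, 8 rose and 1 fell, camera adjusted p = 0.000502, adjusted p = 0.401 with an estimated correlation), with Cd80, a costimulator, at 1.07 ± 0.21. In the myeloid list, of the 15 measured genes, 1 rose, 9 fell and 5 did not pass (camera adjusted p = 0.0428, adjusted p = 0.55 with an estimated correlation), Csf1r, the macrophage growth factor receptor, at -1.69 ± 0.27, and in the thymocyte list of the 16 measured genes, 0 rose, 5 fell and 11 did not pass (adjusted over the list alone, 0 rose and 7 fell, camera adjusted p = 0.0428, adjusted p = 0.53 with an estimated correlation), with Cd8b1 at -1.44 ± 0.23.

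Sex differed fully between these groups: all 3 wild-type libraries carried Y-linked counts and all 3 homozygotes carried Xist, the X-inactivation transcript, which changed by 5.80 ± 1.30. Of the calls, 62 lay on the X and 3 on the Y chromosome. A sex term, chosen after seeing the data, gave 525 calls but rests on 1 heterozygote per sex. Leaving out homozygote 1 gave 2072 calls and leaving out homozygote 10 gave 2074. In +/C313X (2 libraries), edgeR called 0 of 13626 genes, 0 higher and 0 lower, with 440 genes at an unadjusted p under 0.05 and 0 called by DESeq2. Aire changed by 0.01 ± 0.27 on the log2 scale (adjusted p = 1) there.

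Set tests moved in +/C313X without any single call. Tuft genes lay higher (camera adjusted p = 2.39e-05, adjusted p = 0.752 with an estimated correlation), proliferation genes lower (camera adjusted p = 0.00193, adjusted p = 0.752 with an estimated correlation), thymocyte genes lower (camera adjusted p = 0.00268, adjusted p = 0.764 with an estimated correlation) and myeloid genes lower (camera adjusted p = 0.0241, adjusted p = 0.841 with an estimated correlation). No member of these lists passed. The Aire-induced set had 60.2% of its genes below 0 (fry adjusted p = 0.627).

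C442G changes a cysteine that the literature places in the second PHD finger. Homozygotes lost organ transcripts. Keratinocyte-like genes fell and mature mTEC genes rose, in lists that did not pass with an estimated correlation. Heterozygotes, with a normal copy beside the mutant, were changed broadly too, with organ transcripts down. Aire rose by 1.07 ± 0.12 on the log2 scale (adjusted p = 1.03e-08) in homozygotes and by 0.49 ± 0.12 on the log2 scale (adjusted p = 0.00268) in heterozygotes. In homozygotes edgeR called 5802 of 13624 genes, 2655 higher and 3147 lower, and in heterozygotes edgeR called 3610 of 13624 genes, 1784 higher and 1826 lower.

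In homozygotes Ctla4 changed by 3.49 ± 0.23, Fgf10, an epithelial growth factor, by 2.77 ± 0.42 and Syn2, a synaptic vesicle protein, by 2.74 ± 0.14. Ins2 changed by -7.98 ± 0.30, and Prss29, a uterine protease, by -8.05 ± 0.26. Defa21, a gut defensin, was 948-fold (95% counting interval 169 to 37600) lower. Of 28 measured antigen-list members, 1 rose, 24 fell and 3 did not pass (adjusted over the list alone, 1 rose and 25 fell, camera adjusted p = 1.66e-14, adjusted p = 0.00267 with an estimated correlation), and among pancreas genes of the 18 measured, 0 rose, 16 fell and 2 did not pass (camera adjusted p = 2.31e-10, adjusted p = 0.000374 with an estimated correlation). The keratinocyte-like list fell: of the 16 measured, 0 rose, 15 fell and 1 did not pass (adjusted over the list alone, 0 rose and 16 fell, camera adjusted p = 4.46e-07, adjusted p = 0.0776 with an estimated correlation), with Krt10 at -2.12 ± 0.18. In the mature mTEC list, of the 21 measured genes, 13 rose, 1 fell and 7 did not pass (adjusted over the list alone, 15 rose and 1 fell, camera adjusted p = 0.000315, adjusted p = 0.0776 with an estimated correlation). In the tuft list, of the 19 measured genes, 2 rose, 10 fell and 7 did not pass (adjusted over the list alone, 2 rose and 12 fell, camera adjusted p = 0.0392, adjusted p = 0.451 with an estimated correlation), Chat, which makes acetylcholine, at -2.32 ± 0.54.

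In +/C442G, Ctla4 changed by 2.86 ± 0.24, Fam19a1 by 2.36 ± 0.29 and Ptchd4 by 2.09 ± 0.36. The largest falls included genes known from cilia, a group not tested as a list: Mcidas by a log2 change of -4.08 ± 0.47, Zmynd10 by -3.69 ± 0.32 and Dynlrb2 by -3.66 ± 0.50. The mast cell protease Mcpt9 fell by a log2 change of -4.40 ± 0.63 and Inhba, an activin subunit, by -3.83 ± 0.49. Of 28 measured antigen-list members, 2 rose, 20 fell and 6 did not pass (adjusted over the list alone, 2 rose and 21 fell, camera adjusted p = 8.51e-06, adjusted p = 0.0891 with an estimated correlation). Sst changed by -1.57 ± 0.16 and Ins2 by -1.34 ± 0.17. Within the gut list, Reg4, a gut lectin, fell (-2.21 ± 0.18) while Lypd8 and Mttp rose (1.63 ± 0.13 and 1.62 ± 0.16).

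Among pancreas genes in +/C442G, of the 18 measured, 0 rose, 10 fell and 8 did not pass (adjusted over the list alone, 0 rose and 11 fell, camera adjusted p = 0.000268, adjusted p = 0.0242 with an estimated correlation). In the keratinocyte-like list, of the 16 measured genes, 0 rose, 11 fell and 5 did not pass (adjusted over the list alone, 0 rose and 12 fell, camera adjusted p = 0.000197, adjusted p = 0.214 with an estimated correlation), and in the thymocyte list of the 13 measured genes, 0 rose, 3 fell and 10 did not pass (camera adjusted p = 0.0167, adjusted p = 0.383 with an estimated correlation). Of the Aire-induced set, 808 genes fell, 93.9% lay below 0 and the median was -1.10 (fry adjusted p = 9.24e-09). Of the 598 raised genes, 596 were measured and 387 rose.

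V303M lies 10 residues before C313 in the first PHD finger. In homozygotes a few Aire-induced genes of liver, pancreas and other organs fell, and Aire itself did not pass. In total, edgeR called 9 of 13700 genes, 2 higher and 7 lower. The lower genes were Apoa1, a liver apolipoprotein, at -1.49 ± 0.22, Pla2g1b, a pancreatic phospholipase, at -1.28 ± 0.16, the matrix gene Ecm1 at -1.25 ± 0.21, the keratin Krt4 at -1.16 ± 0.18, the steroid enzyme Cyp11a1 at -1.11 ± 0.18, Nppa at -1.08 ± 0.18 and Gpx3, a plasma peroxidase, at -1.08 ± 0.16. Gm15698 rose by 1.22 ± 0.21, and Gm3258 was 29.5-fold (95% counting interval 7.69 to 252) higher, both of unknown function. Aire changed by 0.29 ± 0.13 on the log2 scale (adjusted p = 0.797).

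Of 29 measured antigen-list members, 0 rose, 1 fell and 28 did not pass (adjusted over the list alone, 0 rose and 3 fell, camera adjusted p = 2.47e-08, adjusted p = 0.0614 with an estimated correlation). Immediate-early and heat-shock genes lay higher: of the 17 measured, 0 rose, 0 fell and 17 did not pass (adjusted over the list alone, 3 rose and 0 fell, camera adjusted p = 9.36e-09, adjusted p = 0.0796 with an estimated correlation), and the tuft list lay lower without a call (camera adjusted p = 0.00159, adjusted p = 0.387 with an estimated correlation). Markers of other cells moved too, without a call over all genes. The myeloid list lay lower (camera adjusted p = 0.000153, adjusted p = 0.0796 with an estimated correlation), with Lyz2, a lysozyme, at -0.43 ± 0.13. Cortical epithelial genes lay higher (camera adjusted p = 0.00305, adjusted p = 0.0796 with an estimated correlation), with the chemokine gene Ccl25 at 0.66 ± 0.13, as did proliferation genes (camera adjusted p = 0.00926, adjusted p = 0.387 with an estimated correlation). All 7 lower genes belonged to the Aire-induced set, as did Gm15698, which rose, and of the set 76.5% lay below 0 with a median of -0.28 (fry adjusted p = 0.00226). Leaving out 1 library gave 3 calls without wild type 47, 1 without wild type 49, 3 without wild type 51, 4 without homozygote 40, 60 without homozygote 42 and 0 without homozygote 53. DESeq2 called 43 genes.

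In +/V303M, edgeR called 0 of 13700 genes, with 499 genes at an unadjusted p under 0.05 and 2 called by DESeq2. Aire changed by 0.16 ± 0.13 on the log2 scale (adjusted p = 1). Immediate-early and heat-shock genes again lay higher: of the 17 measured, 0 rose, 0 fell and 17 did not pass (adjusted over the list alone, 8 rose and 0 fell, camera adjusted p = 4.87e-11, adjusted p = 0.192 with an estimated correlation). Antigen genes lay lower (camera adjusted p = 0.00208, adjusted p = 0.205 with an estimated correlation), none of them called, and the Aire-induced set had 66.8% of its genes below 0 (fry adjusted p = 0.0325). Without wild type 51, or without heterozygote 41, 1 gene was called.

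On NOD, Aire-/- was compared with Aire+/-, since no wild type shared its title form. Organ transcripts fell as on B6, MHC class II genes rose, and 9 of 18 interferon-stimulated and 4 of 15 thymocyte genes fell. Aire rose by 0.64 ± 0.18 on the log2 scale (adjusted p = 0.0131), a call that was lost without heterozygote 392 (0.54, adjusted p = 0.0889) or without Aire-/- library 406 (0.59, adjusted p = 0.0517). In total, edgeR called 1842 of 13827 genes, 582 higher and 1260 lower. Serpina9, a protease inhibitor, changed by 2.75 ± 0.33, Hamp, the hepcidin gene, by 2.23 ± 0.43 and Ctla4 by 1.96 ± 0.48. Cyp1a2 had no count in Aire-/- and was at least 58.2-fold lower, as were Vip, a neuropeptide (at least 35.1-fold), and Reg3a, a gut lectin (at least 29.9-fold).

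Of 28 measured antigen-list members, 0 rose, 23 fell and 5 did not pass (adjusted over the list alone, 1 rose and 24 fell, camera adjusted p = 6.93e-22, adjusted p = 0.00869 with an estimated correlation), with S100a9, a neutrophil calprotectin subunit, at -2.95 ± 0.29. Liver genes fell: of the 16 measured, 0 rose, 14 fell and 2 did not pass (camera adjusted p = 1.01e-12, adjusted p = 0.000922 with an estimated correlation). Pancreas genes fell: of the 19 measured, 0 rose, 16 fell and 3 did not pass (camera adjusted p = 8.2e-20, adjusted p = 0.00294 with an estimated correlation), with the trypsin gene Prss2 at -4.91 ± 0.51. Of 21 measured mature mTEC genes, 5 rose, 0 fell and 16 did not pass (camera adjusted p = 0.00037, adjusted p = 0.049 with an estimated correlation), H2-Ab1 at 0.79 ± 0.16. In the interferon list, of the 18 measured genes, 1 rose, 9 fell and 8 did not pass (adjusted over the list alone, 1 rose and 12 fell, camera adjusted p = 5.77e-05, adjusted p = 0.0908 with an estimated correlation), with Isg15 at -1.18 ± 0.18. In the thymocyte list, of the 15 measured genes, 0 rose, 4 fell and 11 did not pass (adjusted over the list alone, 0 rose and 6 fell, camera adjusted p = 0.0059, adjusted p = 0.42 with an estimated correlation), with the T cell receptor subunits Cd3g and Cd3d at -1.98 ± 0.42 and -1.50 ± 0.34. Myeloid genes went both ways: of the 17 measured, 3 rose, 6 fell and 8 did not pass (adjusted over the list alone, 3 rose and 7 fell, camera adjusted p = 0.355, adjusted p = 0.723 with an estimated correlation), Itgam at -1.99 ± 0.50 and Batf3 at 1.11 ± 0.20.

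The +/C313Y mice asked whether a single copy of a PHD finger change, beside a normal copy, disturbs AIRE. It did so broadly: against wild type, edgeR called 2402 of 13827 genes, 880 higher and 1522 lower, and 1384 genes were called with only the compared groups in the fit. Organ transcripts and interferon-stimulated genes fell. Aire rose by 0.62 ± 0.14 on the log2 scale (adjusted p = 0.00224). Htra4, a placental protease, changed by 4.03 ± 0.32, Fhad1 by 3.48 ± 0.25, Ly9, a lymphocyte receptor, by 2.37 ± 0.23 and Orm1, an acute phase protein, by 2.36 ± 0.31. Kiss1, which encodes kisspeptin, had no count in the mutant and was at least 24.7-fold lower, and Sohlh1, a germ cell factor, was 201-fold (95% counting interval 35.7 to 7950) lower.

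Of 28 measured antigen-list members, 0 rose, 25 fell and 3 did not pass (adjusted over the list alone, 0 rose and 26 fell, camera adjusted p = 1.05e-20, adjusted p = 0.0109 with an estimated correlation), with Ppy at -3.98 ± 0.39. In the interferon list, of the 18 measured genes, 1 rose, 14 fell and 3 did not pass (adjusted over the list alone, 1 rose and 15 fell, camera adjusted p = 5.42e-07, adjusted p = 0.0416 with an estimated correlation), with Ifit3 at -2.40 ± 0.35 and Mx2, an antiviral GTPase, at -1.92 ± 0.21. In the fibroblast and endothelial list, of the 11 measured genes, 0 rose, 3 fell and 8 did not pass (adjusted over the list alone, 0 rose and 5 fell, camera adjusted p = 0.00795, adjusted p = 0.0857 with an estimated correlation), with Col1a1 at -3.12 ± 0.36. In the keratinocyte-like list, of the 16 measured genes, 5 rose, 0 fell and 11 did not pass (camera adjusted p = 0.169, adjusted p = 0.677 with an estimated correlation), with Spink5, an epidermal protease inhibitor, at 1.37 ± 0.20.

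Mice with 1 null and 1 C313Y allele asked what C313Y does alone. Against their wild type, edgeR called 3138 of 13827 genes, 1359 higher and 1779 lower, and Aire rose by 0.67 ± 0.18 on the log2 scale (adjusted p = 0.00599). Cd86 and Cd80, costimulators of T cells, changed by 2.08 ± 0.41 and 1.71 ± 0.32, Cbln4, a synapse organiser, by 4.30 ± 0.61 and Hamp by 3.26 ± 0.45. Without a count in the mutant were Smr3a, a salivary gene (at least 34.1-fold lower), Cryba1, a lens crystallin (at least 30.6-fold lower), and Fev, a serotonergic factor (at least 24.8-fold lower).

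Of 28 measured antigen-list members, 1 rose, 24 fell and 3 did not pass (adjusted over the list alone, 1 rose and 26 fell, camera adjusted p = 2.36e-17, adjusted p = 0.0216 with an estimated correlation). In the mature mTEC list, of the 21 measured genes, 10 rose, 0 fell and 11 did not pass (adjusted over the list alone, 11 rose and 0 fell, camera adjusted p = 1.72e-05, adjusted p = 0.0246 with an estimated correlation). In the interferon list, of the 18 measured genes, 2 rose, 13 fell and 3 did not pass (camera adjusted p = 1.25e-05, adjusted p = 0.0818 with an estimated correlation).

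The direct test of a dominant effect on NOD set +/C313Y against Aire+/-, since each has a single normal copy. Organ transcripts were far lower in +/C313Y, and a part of the tuft, keratinocyte-like and fibroblast genes was lower too. The tuft and keratinocyte-like lists did not pass with an estimated correlation, and against wild type 5 keratinocyte-like genes had risen. Aire was higher by 0.85 ± 0.17 on the log2 scale (adjusted p = 0.000592), and edgeR called 2187 of 13827 genes, 559 higher and 1628 lower. Abcb4, a bile lipid transporter, changed by 3.37 ± 0.43 and Htra4 by 3.12 ± 0.36, while Sycn, a pancreatic granule protein, had no count in +/C313Y and was at least 23.8-fold lower. Of 28 measured antigen-list members, 0 rose, 26 fell and 2 did not pass (adjusted over the list alone, 0 rose and 28 fell, camera adjusted p = 1.1e-24, adjusted p = 0.00521 with an estimated correlation), with Fabp2 at -4.56 ± 0.43. In the tuft list, of the 19 measured genes, 0 rose, 8 fell and 11 did not pass (adjusted over the list alone, 0 rose and 10 fell, camera adjusted p = 0.000259, adjusted p = 0.197 with an estimated correlation), with Ptgs1, the prostaglandin enzyme COX-1, at -1.67 ± 0.24. In the keratinocyte-like list, of the 16 measured genes, 0 rose, 8 fell and 8 did not pass (adjusted over the list alone, 0 rose and 10 fell, camera adjusted p = 1.65e-05, adjusted p = 0.0952 with an estimated correlation), with Ivl, the involucrin gene, at -1.59 ± 0.37. In the fibroblast and endothelial list, of the 11 measured genes, 0 rose, 5 fell and 6 did not pass (adjusted over the list alone, 0 rose and 7 fell, camera adjusted p = 0.000362, adjusted p = 0.0242 with an estimated correlation). The compared groups differ in title form, and no fit can separate that from genotype.

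The Aire-induced set took 3.884% ± 0.503 (SD, n = 3) of the counts of B6 wild-type libraries and 0.874% ± 0.0358 (n = 4) of Aire-/-, which chose it. In lines that did not choose it, its share fell to 15.5% of the wild-type share in Y86C, 23.7% in C313X and 20.7% in C442G homozygotes, and to 38.1% in -/C313Y. V303M homozygotes kept 81%, and NOD Aire-/- held 44.4% of the share in Aire+/-. Heterozygotes kept 87.4% for the null, 81.6% for Y86C, 96.2% for C313X and 90.4% for V303M, but 54.9% for C442G and 47.5% for C313Y. Against Aire+/-, +/C313Y held 46.8%, but 92.18% (exact p = 0.0857) when the set was chosen without a fold limit, which also takes in genes that fell little. A second set, chosen after the data were seen from the Y86C and C442G homozygotes, gave 47.9% (exact p = 0.0286). Two-sided exact permutation tests gave p = 0.0119 for C442G homozygotes, 0.0179 for +/C442G, 0.00794 for +/C313Y against wild type and 0.0286 against Aire+/-, with the smallest Benjamini-Hochberg adjusted p over 14 tests at 0.0556. With 3 libraries against 3 the exact test cannot go below 0.1, and that value was reached for Y86C, C313X homozygotes, V303M, NOD Aire-/- and -/C313Y.

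**Figure D3:**
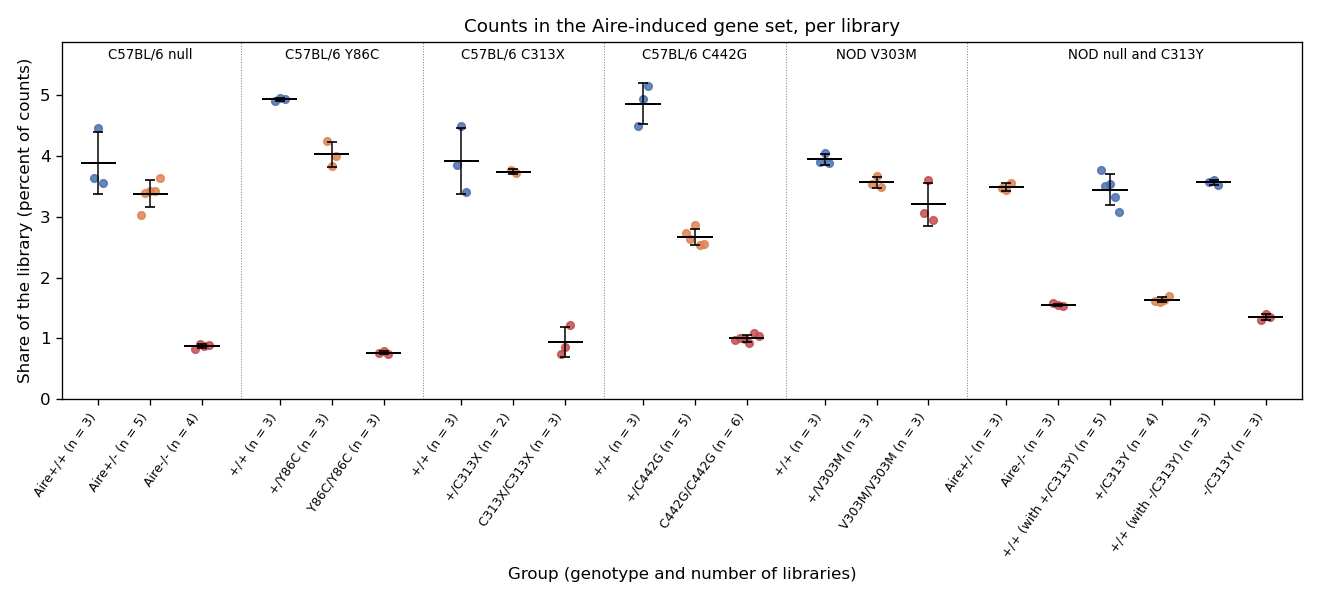
Percent of a library's counts in the Aire-induced set of 1294 genes (vertical axis), by group (horizontal axis), with dots for libraries, black lines for group means and error bars for 1 SD. Libraries of +/C442G lie between 2.54% and 2.86%, below every wild-type library of their line and above every homozygote.

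All 5 +/C442G libraries and all 3 +/Y86C libraries had set shares between every homozygous and every wild-type library of their line. The same held for 4 of 5 Aire+/- libraries, 1 of 3 +/V303M libraries and 0 of 2 +/C313X libraries. At equal depth, the number of detected genes fell in the groups with the lowest shares: Aire-/- libraries differed from wild type by -1011.1 genes (exact p = 0.0286), C442G homozygotes by -1286 (exact p = 0.0119), +/C442G by -398.13 (exact p = 0.0179) and +/C313Y by -880.8 (exact p = 0.00794). Homozygotes of Y86C (-1659.3) and C313X (-1258.7), -/C313Y (-1199.7) and NOD Aire-/- (-1180.3) fell as well (exact p = 0.1 each). Among groups that kept at least 81% of the share, +/C313X differed by 187 (exact p = 0.4), +/V303M by -238 (exact p = 0.1), V303M homozygotes by -195 (exact p = 0.2), +/Y86C by -85.667 (exact p = 0.1) and Aire+/- by -82.333 (exact p = 0.0893). The smallest adjusted p over these 15 tests was 0.0595.

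Dnmt3l, the gene that overlaps the 5' end of Aire, rose with copies of the null allele. In B6 it ranged from 34.3 to 49.2 CPM in 3 wild-type libraries and averaged 90.5 ± 19.4 CPM (SD, n = 5) in Aire+/- and 166 ± 11.5 (n = 4) in Aire-/-. On NOD it was 105 ± 7.73 in Aire+/- and 213 ± 23.9 in Aire-/- (n = 3 each), against 47.2 ± 11.7 (n = 5) and 50.9 ± 15.3 (n = 3) in wild types. The +/C313Y libraries held 42.8 ± 13 CPM (n = 4) and the -/C313Y libraries, with 1 null copy, 121 ± 4.77 (n = 3). Outside the B6 heterozygote comparison this gene was chosen after its values were seen. Its log2 change was 2.13 ± 0.16 in B6 Aire-/-, 1.18 ± 0.21 in NOD Aire-/- against Aire+/-, 1.36 ± 0.22 in -/C313Y and -0.03 ± 0.19 in +/C313Y. Without a null allele it also rose in Y86C homozygotes (1.12 ± 0.13), +/Y86C (0.64 ± 0.13) and C442G homozygotes (0.88 ± 0.13). In C313X homozygotes it was higher in every library than in wild type, but the change (0.82 ± 0.33, adjusted p = 0.106) did not pass. Whether counting used strand is not stated.

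**Figure D4:**
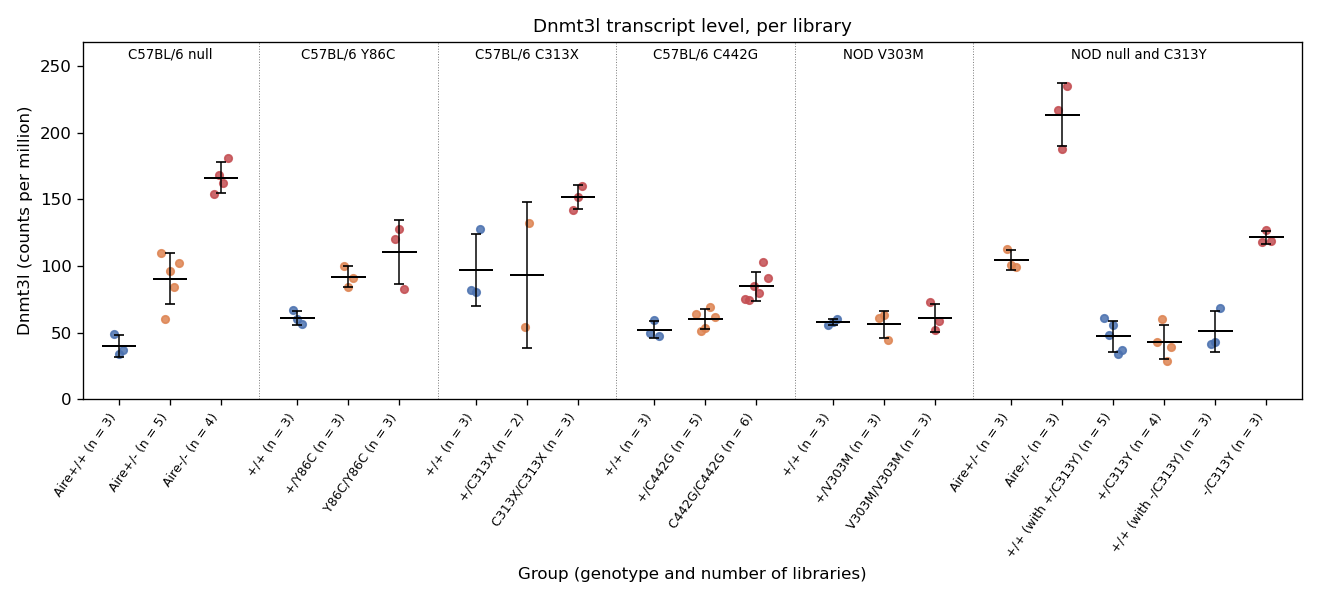
Dnmt3l level in CPM (vertical axis) in each library, by group (horizontal axis), with dots for libraries, black lines for group means and error bars for 1 SD. The NOD Aire-/- group has the highest mean, 213 CPM, while wild-type libraries of the B6 null line lie between 34.3 and 49.2 CPM.

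The next neighbour, Icosl, also chosen after its values were seen, changed by 1.63 ± 0.12 in Y86C homozygotes, 1.10 ± 0.13 in C442G homozygotes and 0.78 ± 0.11 in B6 Aire-/-.

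Tests of differences asked whether an allele acts otherwise than the null in the same dose on B6, each against its own wild type. All subtract an effect of the same null line, so they are not independent. A shift in that line, whose wild types all carried Xist, would show in each. In heterozygotes, Y86C differed from the null in no gene: edgeR called 0 of 14547 genes, with 540 at an unadjusted p under 0.05 and 0 called by DESeq2. For C313X, edgeR called 0 of 14547 genes, with 1327 at an unadjusted p under 0.05 and 29 called by DESeq2. For C442G, edgeR called 837 of 14547 genes, 326 higher and 511 lower, so +/C442G went well beyond the loss of a copy. Aire did not differ in any of these heterozygote tests, with 0.29 ± 0.20 for C442G (adjusted p = 0.451).

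In the C442G heterozygote difference, Ctla4 was higher by 2.79 ± 0.65 and Cd83, a marker of mature antigen-presenting cells, by 1.08 ± 0.30, while Inhba was lower at -3.65 ± 0.84 and Lce1i, a cornified envelope gene, at -4.20 ± 0.68. Of 29 measured antigen-list members, 0 rose, 7 fell and 22 did not pass (adjusted over the list alone, 1 rose and 14 fell, camera adjusted p = 1.44e-05, adjusted p = 0.0201 with an estimated correlation), with Csn1s2a at -2.46 ± 0.41. In the milk and salivary list, of the 18 measured genes, 0 rose, 6 fell and 12 did not pass (adjusted over the list alone, 1 rose and 10 fell, camera adjusted p = 1.44e-05, adjusted p = 0.0201 with an estimated correlation). In the tuft list, of the 19 measured genes, 0 rose, 2 fell and 17 did not pass (adjusted over the list alone, 0 rose and 8 fell, camera adjusted p = 1.44e-05, adjusted p = 0.197 with an estimated correlation), with Ptgs1 at -1.09 ± 0.28. In the keratinocyte-like list, of the 16 measured genes, 0 rose, 2 fell and 14 did not pass (adjusted over the list alone, 0 rose and 8 fell, camera adjusted p = 7.95e-06, adjusted p = 0.156 with an estimated correlation). Of the Aire-induced set, 308 of 1276 measured genes were lower and 87.3% lay below 0, with a median of -0.88 (fry adjusted p = 3.5e-09). With another scaling (RLE) the lower share of calls was 72.2% instead of 61.1%. Leaving out null-line wt_430 gave 516 calls.

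In homozygotes, the Y86C effect on Aire itself exceeded that of the null by 0.76 ± 0.21 on the log2 scale (adjusted p = 0.0487). That call was lost in 12 of 13 fits that left out 1 library, with RLE factors (adjusted p = 0.0811) and with DESeq2 (adjusted p = 0.0569). In total, edgeR called 291 of 14547 genes, 162 higher and 129 lower, with 79 (without Y86C homozygote 4) to 264 calls when 1 library was left out. Tuft and pancreas genes were lower than in the null: of the 19 measured tuft genes, 0 rose, 6 fell and 13 did not pass (adjusted over the list alone, 1 rose and 12 fell, camera adjusted p = 5.17e-10, adjusted p = 0.0339 with an estimated correlation), with Avil, an actin regulator, at -2.40 ± 0.54 and Rgs13 at -2.14 ± 0.54. Among pancreas genes, of the 19 measured, 0 rose, 4 fell and 15 did not pass (adjusted over the list alone, 0 rose and 6 fell, camera adjusted p = 3.94e-05, adjusted p = 0.0123 with an estimated correlation), with Pyy at -3.23 ± 0.63 and the colipase gene Clps at -2.27 ± 0.61. Of 29 measured antigen-list members, 1 rose, 0 fell and 28 did not pass (adjusted over the list alone, 1 rose and 7 fell, camera adjusted p = 2.41e-09, adjusted p = 0.0016 with an estimated correlation), Reg3g, a gut lectin, being the member that rose (1.09 ± 0.29). In the mature mTEC list, of the 21 measured genes, 1 rose, 0 fell and 20 did not pass (adjusted over the list alone, 9 rose and 2 fell, camera adjusted p = 0.000147, adjusted p = 0.0941 with an estimated correlation), with H2-Eb1 at 0.98 ± 0.20. Cd200, an inhibitory surface protein, was higher by 1.75 ± 0.36, Ube2l6, an enzyme of ISG15 conjugation, by 1.86 ± 0.46 and Calca, the calcitonin gene, by 1.07 ± 0.23. The lower share of calls was 44.3%, but 63.5% with RLE scaling and 60.2% with DESeq2.

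In C313X homozygotes, edgeR called 392 of 14547 genes, 278 higher and 114 lower, with 162 (without C313X wild type 6) to 928 calls (without C313X wild type 2) when 1 library was left out. Macrophage genes lower than in the null were Csf1r at -1.85 ± 0.35 and the complement genes C1qa and C1qb at -1.50 ± 0.41 and -1.17 ± 0.31. In the myeloid list, of the 16 measured genes, 0 rose, 4 fell and 12 did not pass (adjusted over the list alone, 0 rose and 11 fell, camera adjusted p = 5.03e-07, adjusted p = 0.182 with an estimated correlation), and in the thymocyte list of the 16 measured genes, 0 rose, 1 fell and 15 did not pass (camera adjusted p = 0.000527, adjusted p = 0.232 with an estimated correlation), with Lck at -1.19 ± 0.33. Calca was higher by 1.81 ± 0.23 and Chga, a granule protein, by 1.06 ± 0.24, and Clps was lower at -2.91 ± 0.81. In the tuft list, of the 19 measured genes, 1 rose, 2 fell and 16 did not pass (adjusted over the list alone, 1 rose and 6 fell, camera adjusted p = 6.33e-05, adjusted p = 0.232 with an estimated correlation). Sex differs between the C313X groups, and with a sex term 136 genes were called.

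In C442G homozygotes, edgeR called 423 of 14547 genes, 226 higher and 197 lower, with 217 (without KO_429) to 456 calls (without C442G wild type 88) when 1 library was left out. Of the tuft genes, 4 were lower than in the null, among them Avil at -1.88 ± 0.47, Ptgs1 at -1.32 ± 0.27 and Ltc4s, a leukotriene synthase, at -1.77 ± 0.36, while Spib, a transcription factor of that list, was higher (0.74 ± 0.14). In the tuft list, of the 19 measured genes, 1 rose, 4 fell and 14 did not pass (adjusted over the list alone, 1 rose and 10 fell, camera adjusted p = 8.08e-06, adjusted p = 0.282 with an estimated correlation). Calca was higher by 1.73 ± 0.22, Reg3g by 1.16 ± 0.27 and Crp, an acute phase gene, by 2.02 ± 0.41, while haptoglobin, Hp, was lower at -3.55 ± 0.56. The lower share of calls was 46.6%, 63.7% with RLE scaling and 58.7% with DESeq2.

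Across genes, which are not independent replicates, the log2 changes of B6 Aire-/- correlated with those of Y86C (Pearson r = 0.897), C442G (0.891) and C313X (0.858) homozygotes, and with -/C313Y (0.825), NOD Aire-/- (0.804), +/C313Y (0.756) and +/C442G (0.74). Of the genes tested in both, 1880 fell in Aire-/- and Y86C, against 595 for independent lists, and 1712 rose, against 511. For +/C442G, 1109 fell in both, against 298. For C313X 1195 fell in both, against 302, and for NOD Aire-/- 833, against 189. NOD Aire-/- and +/C313Y shared 969 falling genes, against 139, with r = 0.794. The heterozygous effects of the null and C442G on B6 correlated at r = 0.345, with 37 genes higher in both against 6.69 for independent lists.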

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

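All tests of explanations, and those on other splits of the libraries, were chosen after the results were seen, while the tests of differences between alleles were fixed before. Several effects differed between alleles on B6. The heterozygous effect of C442G differed from that of the null in 837 genes. The homozygous effects differed from the null in 291 genes for Y86C, 392 for C313X and 423 for C442G. Aire itself rose more in Y86C homozygotes than in the null, by a further 0.76 on the log2 scale, a call that 12 of 13 fits without 1 library lost. One library outside all groups, titled Aire_wt_438, had an Aire level of 2264 CPM, within the range of the B6 groups.

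The first pattern is that +/C442G lowers the Aire-induced set more than the loss of 1 copy does. If the loss of 1 functional copy were all, +/C442G and Aire+/- would move the set alike, yet the median log2 difference of the set between these effects was -0.876. Homozygous libraries labelled heterozygous would show homozygous shares, but 5 of 5 +/C442G libraries lay between all homozygous and all wild-type libraries. Total Aire transcript was not lower, since Aire rose by 0.492 on the log2 scale in +/C442G. The counts sum both alleles, so less transcript of the normal allele cannot be excluded. A candidate explanation left open is that the mutant protein interferes with the normal one, which no protein measurement here tests. These tests do not cover +/C313Y. It held 47.5% of the share in wild types of its own title form and 46.8% of that in Aire+/-, 47.9% with the second set, but 92.18% (exact p = 0.0857) with no fold limit. Title form would need to raise the share in Aire+/- about 2-fold, while wild types of 2 other title forms held 3.446% and 3.562%. This argues against title form, but no wild type shares that of Aire+/-.

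The second pattern is that Dnmt3l, the neighbour of Aire, rises with copies of the null allele. Loss of Aire function as the whole cause would raise it in +/C313Y at least as in Aire+/-, but it was lower there by a log2 change of -1.16. Aire reads counted for Dnmt3l would lift it wherever Aire rose, but its change in +/C313Y was -0.0285 while Aire rose. The smallest rise over the 4 comparisons that add 1 null copy was 0.953, which restates the pattern and tests no cause. An action of the null allele on its neighbour thus stays open, and the construct of the allele is not in the labels. Dnmt3l also rose in Y86C and C442G homozygotes and +/Y86C. It lay higher in every C313X homozygote than in wild type, but changed by -0.551 with a sex term resting on 1 heterozygote per sex. None of these carry a null allele, so a part played by lost Aire function on B6 stays open.

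The third pattern is that the deposited comparison columns of the B6 null table run against the titles. With the names of heterozygote and wild type exchanged, a DESeq2 refit matched the deposited log2 fold changes to a largest median absolute difference of 1.82e-06. If the library titles themselves were exchanged, Dnmt3l would be lower in titled heterozygotes, but it was higher by 1.18 on the log2 scale. The titles were used throughout, and an exchange of names in those columns is the explanation that the values favour.

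Other splits of the same libraries show how often another grouping gives as many calls. For B6 Aire-/- against wild type the real split gave 4650 calls and the highest other split 2095 (1 of 35 splits as large, the real one). The same held for Aire+/- with 61 against 26 (1 of 56), Aire-/- against Aire+/- with 4287 against 2187 (1 of 100), C442G homozygotes with 5802 against 1 (1 of 84) and +/C442G with 3610 against 182 (1 of 56). It also held for +/C313Y against wild type with 2402 against 1507 (1 of 100). Against Aire+/-, +/C313Y had 2187 against 1290 (1 of 35). In each of these only the real split reached its count, but the shares were not adjusted over the tests. Aire+/- gave 15 calls without wt_434, fewer than its highest other split. Chance is thus less likely for these counts but not excluded. With 3 libraries against 3 there are too few splits, 10, for a share under 0.05. The real and highest other counts were 6599 and 0 for Y86C homozygotes, 448 and 0 for +/Y86C, 3147 and 0 for C313X homozygotes, 9 and 1 for V303M homozygotes, 1842 and 0 for NOD Aire-/-, and 3138 and 0 for -/C313Y.

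For 6 other counts the splits decide nothing. With a real count of 0 every split is as large by construction. This holds for +/V303M, with 0 calls by edgeR (499 genes at an unadjusted p under 0.05, and 2 called by DESeq2), the highest other 1, and 10 of 10 splits as large. It also holds for the heterozygous difference of Y86C from the null, with 0 calls by edgeR (540 genes at an unadjusted p under 0.05, and 0 called by DESeq2), the highest other 11, and 40 of 40 splits as large. Splits of the other differences shuffle each line separately, so they can keep or remove either genotype effect and do not isolate the difference. For the heterozygous difference of C442G, 1 of 40 splits, the real one, gave as many calls (837 real, 20 highest other). In the homozygous differences, 12 of 40 splits gave as many calls for Y86C (291 real, 4624 highest other), 4 of 40 for C313X (392 and 2037) and 6 of 40 for C442G (423 and 5097). The highest splits for Y86C and C442G kept the true labels of 1 line, so their counts hold its genotype effect.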

How the results depend on the processing

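Tests with a sex term, without libraries titled C313T or with a second Aire-induced set were chosen after seeing the results, the others before. Of 231 alternatives for the Aire level, 209 kept direction and side of the threshold, 16 ended a call, 1 made one and 5 reversed a value. Of 160 for the set share, by unadjusted exact p, 136 kept both, 23 no longer passed and 1 reversed. None passed after adjustment, and the smallest groups cannot pass. Counts of called genes moved over 1.5 times in 60 of 291. Causes of changes below were not tested, except that fewer libraries lower the power.

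With a sex term the calls were 525 for C313X homozygotes, 2 for V303M homozygotes, 1 for the heterozygous and 136 for the homozygous difference of C313X. With only the compared groups in the fit they were 1 for V303M homozygotes and 1384 for +/C313Y against wild type. DESeq2 called 43 genes in V303M homozygotes, 2 in +/V303M and 29 in the heterozygous difference of C313X. With all 8 wild-type libraries as control, NOD Aire-/- had 4447 calls. The excess of Aire in Y86C homozygotes over the null was 0.69 with RLE factors (adjusted p = 0.0811) and with DESeq2 (adjusted p = 0.0569).

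The set share of Aire+/- was 90.35% of wild type without the 5 most abundant genes (exact p = 0.0714) and 94.45% with the second set (exact p = 0.339). With no fold limit, +/C313Y held 92.18% of the share in Aire+/- (exact p = 0.0857). The difference in detected genes for Aire+/- was -175.5 at a minimum of 3 counts (exact p = 0.0357).

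With an estimated correlation, the number of list tests that passed was 5 for B6 Aire-/- and 0 for Aire+/- against wild type, 7 for Aire-/- against Aire+/-, 6 for Y86C homozygotes and 0 for +/Y86C, 4 for C313X homozygotes and 0 for +/C313X, 5 for C442G homozygotes and 1 for +/C442G, 0 for V303M homozygotes and 0 for +/V303M. It was 6 for NOD Aire-/-, 6 for +/C313Y and 5 for -/C313Y against wild type, 7 for +/C313Y against Aire+/-, and for differences 0 for +/Y86C, 2 for +/C442G, 5 for Y86C, 0 for C313X and 0 for C442G homozygotes. The camera test of the Aire-induced set then gave a probability of 0.398 in +/C313X, and for differences 0.264 for +/C313X, 0.157 for C313X and 0.0508 for C442G homozygotes.

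Leaving out 1 library gave these ranges of calls. Aire+/- against wild type ran from 15 (without wt_434) to 82 (without het_433), +/Y86C from 218 (wild type 3) to 461 (wild type 1), C313X homozygotes from 2072 (homozygote 1) to 2950 (wild type 7), V303M homozygotes from 0 (homozygote 53) to 60 (homozygote 42). In +/C313X 0 to 1 genes were called (1 without wild type 6 or heterozygote 3), and in +/V303M 0 to 1. Where +/C313X keeps 1 library, it is assumed to vary like the other groups. Counts of 0 are from edgeR, beside 440 genes at an unadjusted p under 0.05 and 0 called by DESeq2 for +/C313X.

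For heterozygous differences, Y86C ran from 0 to 1 (without null-line het_435) and C313X from 0 to 297, with 297 without C313X wild type 2, 226 without C313X heterozygote 8, 76 without C313X wild type 7 and 1 without null-line het_435. C442G ran from 516 (null-line wt_430) to 905 (C442G heterozygote 85). The homozygous difference of Y86C ran from 79 to 264, with 79 without Y86C homozygote 4, 161 without homozygote 5, 121 and 159 without its wild types 2 and 3, 140, 172 and 163 without null-line wt_430, wt_432 and wt_434, 141 without KO_429 and 264 without KO_431. That of C313X ran from 162 to 928, with 928, 162 and 600 without its wild types 2, 6 and 7, 183 and 246 without its homozygotes 1 and 10, 182, 234 and 205 without null-line wt_430, wt_432 and wt_434, and 197 and 257 without KO_429 and KO_436. That of C442G ran from 217 (KO_429) to 456 (C442G wild type 88), with 241, 251 and 251 without null-line wt_430, wt_432 and wt_434 and 225 and 264 without C442G wild types 86 and 89.

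For Aire, +/C313X ran from -0.52 without heterozygote 8 to 0.39 without heterozygote 3, with -0.11 and -0.09 without wild types 2 and 6. NOD Aire-/- ran from 0.54 (heterozygote 392) to 0.73 (heterozygote 395). Differences ran from -0.74 (heterozygote 8) to 0.20 (heterozygote 3) for +/C313X, with 0.07 without wild type 7, from 0.69 (KO_429) to 0.83 (KO_428) for Y86C homozygotes, where 12 of 13 fits lost the call, and from 0.37 (wild type 2) to 0.77 (wild type 7, adjusted p = 0.0229) for C313X homozygotes. The set share in percent of control ran from 21.67 to 24.3 for B6 Aire-/-, 83.71 to 93.88 for Aire+/-, 90.02 to 103.3 for +/C313X (103.3 without wild type 6) and 46.23 to 47.26 for +/C313Y against Aire+/-. The difference in detected genes ran from -1046 to -984 for Aire-/-, -98.5 to -55.33 for Aire+/- and -1056 to -937.3 for +/C313Y against Aire+/-.

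For the named genes, 2300 of 2503 alternatives kept direction and side of the threshold, 194 ended a call, 3 made one and 6 reversed a value. The ended calls lay mostly in V303M homozygotes (50 of 120 alternatives), the homozygous differences of C313X (40 of 119) and Y86C (39 of 153), Aire+/- (25 of 140) and +/Y86C (18 of 136). In V303M homozygotes Nppa, Ecm1, Cyp11a1 and Gm15698 each lost the call in 7 of 11 alternatives, and Apoa1 and Gpx3 in 5. In the Y86C difference Reg3g lost it in 12 of 17 and Clps in 10, and in the C313X difference Clps in 11, C1qa in 10, and Lck and C1qb in 9. In Aire+/- Samd15 lost it in 8 of 12 and Cxcl1 in 7 of 13. The named genes other than Aire of B6 Aire-/-, Y86C and C442G homozygotes, +/C442G, NOD Aire-/- and -/C313Y lost the call in none of the alternatives run. In C313X homozygotes Dnmt3l, not called, was -0.551 with a sex term instead of 0.82. The value of Dnmt3l in +/C313Y against wild type, which was not called, reversed from -0.03 to 0.0921 without the libraries titled C313T, and ran from -0.24 (heterozygote 53) to 0.13 (heterozygote 73) when 1 library was left out, above 0 also without wild types 45 (0.05) and 52 (0.06) and heterozygote 75 (0.02).

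With a replicate block of the numbers 1 to 3, -/C313Y had 3608 calls instead of 3138. The correlations of same-numbered libraries were 0.0637, -0.0377 and 0.158, and not every library correlated best with its own number, so the numbers were not taken to pair them. In simulated data with the depth and group sizes of these libraries, edgeR recovered 17.9% of 2-fold changes for +/C313X, 47.8% for V303M homozygotes and 55.2% for +/V303M. Depth alone was not varied.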

Other observations

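The tests of genes, lists and differences named here were fixed before the data were examined. Setting them side by side, and all other values here, were chosen after the results were seen. No explanation is offered for the patterns. Across alleles on 2 backgrounds, cells that lost organ transcripts kept or raised the transcript of Aire itself. Ctla4, Fam19a1 and Ptchd4 rose together in B6 Aire-/-, Y86C and C442G homozygotes, and Ctla4 and Fam19a1 rose in NOD Aire-/- as well.

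Against the same null line, some tuft genes were lower in Y86C, C313X and C442G homozygotes and +/C442G. Of these, only the Y86C difference passed for the tuft list with an estimated correlation. Ptgs1 and Bmx rose in Aire-/-, and Bmx in Aire+/-, against the same wild types. Y86C homozygotes lowered most of the list, and 6 differences were called. Isg15 fell in B6 and NOD Aire-/-, in Y86C and C442G homozygotes, and in +/C313Y and -/C313Y, but Ifit1 rose in B6 Aire-/- and Cxcl10 in NOD Aire-/-. The interferon list as a whole did not pass with an estimated correlation in B6 Aire-/-, NOD Aire-/- and -/C313Y, and in V303M homozygotes it did not pass with either.

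The library Aire_wt_438, titled wild type with the genotype label Aire -/-, had 2012668 counts. Aire stood at 2264 CPM, the Aire-induced set at 4.136% of counts, and 15648 genes were detected. Dnmt3l stood at 48.2 CPM, Xist at 4.97 CPM and Y-linked genes together at 143 CPM. Per the titles it belongs with the wild types, whose set share averaged 3.884%, and per the genotype label with the homozygotes, which averaged 0.874%.

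The second Aire-induced set, of 1702 genes called in both Y86C and C442G homozygotes, shared 1039 genes with the first. The deposited adjusted p-values of Y86C homozygotes marked 735 genes, while adjusting the deposited p-values anew marked 6489. For +/C313X these numbers were 5 and 0, for V303M homozygotes 85 and 45, and for +/V303M 8 and 3. The authors' ComBat values in the shared NOD table moved 6 libraries titled with the numbers 1 to 3 apart from the other 15. NOD heterozygote 392 of the null line held both Xist (83.1 CPM) and Y-linked counts (38.8 CPM), as did NOD wild type 52 (41.9 and 49 CPM).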
